A study of Oryza sativa with 2 samples.

How the data were processed

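The series compared shoots of 7-day-old rice seedlings (Oryza sativa, cultivar Kita-ake, grown on MS medium) that overexpress a truncated form of OsbZIP39 with wild-type shoots. OsbZIP39 is a bZIP transcription factor of the endoplasmic reticulum (ER) stress response, and the suffix deltaC in the labels is read here as a C-terminal truncation, which the labels do not spell out. Total RNA was hybridised to 2 two-colour Agilent oligonucleotide arrays, 1 for overexpressor line 12 (replicate 1) and 1 for line 28 (replicate 2). Per the labels, wild-type RNA carried Cy3 (green) and overexpressor RNA carried Cy5 (red) on both arrays, so the dyes were never swapped and dye and genotype cannot be told apart. The design text of the series speaks of 4 biological replicates, and 2 arrays were analysed here. Both lines formed 1 group, and the wild type entered as the other channel of each array, so each value is a ratio of overexpressor to wild type. The labels call the lines independent but do not say whether each sample was 1 plant or a pool. The p-values of single genes rest only on the spread between these 2 samples, moderated by a prior spread pooled over all measured probes. An error that both arrays share, such as that of any shared wild-type RNA, is not in that spread. Per the file headers both arrays lay on 1 slide and shared 1 scan, so no slide or scan effect could be tested.

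Spot intensity values were made with Agilent Feature Extraction 10.5.1.1, per the file headers: the mean pixel brightness of each spot and the median of its local background in each channel. The processed intensity values in the same files were background-subtracted, spatially detrended and dye-normalized by linear and LOWESS scaling, with substitutes for dim spots, per the file headers. The log10 ratio in each file is red over green of those processed values, per the file headers. The deposited table of log10 ratios for the whole series was set against the files' own log10 ratios by feature number. Its values differed from them by at most 0.00499, so its scale (log10), direction (overexpressor over wild type) and lack of further centring are known, and the median of each column was 0. No value column was left unmapped.

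Each array held 45151 spots, of which 43144 carried gene probes. The median gene spot had a wild-type signal of 308 and an overexpressor signal of 689 on the line 12 array, against backgrounds of 27 and 59. On the line 28 array these signals were 267 and 599, against backgrounds of 28 and 58. Of the gene spots, 76.5% (line 12 array) and 75.0% (line 28 array) were well above background in the wild-type channel, and 78.3% and 77.0% in the overexpressor channel. No gene spot was saturated, and 10 and 8 gene spots that the scanner software marked as non-uniform outliers were left out. The slope of observed on expected log ratios of the spike-in controls was 0.866 and 0.889, where uncompressed ratios give 1. Repeat spots of a probe had a median SD of 0.0225 and 0.0239 (log2 ratio, 2867 probes), and the number of arrays, not spot noise, limits the precision.

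From the mean and background intensities, background was corrected with normexp (offset 50), and red over green was normalized within each array by loess, with control spots and outliers at weight 0 (limma 3.58.1, R 4.3.3). Some 60-base probes were printed under several names, so a probe was taken as a distinct 60-base sequence and its spots were averaged. Of 37896 such probes, 37603 stood under 1 gene, while 1 was printed under 50. Only probes under 1 gene gave gene values. A probe counted as measured when it was well above background in at least 1 channel on both arrays, which 28989 probes met. These covered 21690 genes, each represented by its brightest probe. The log2 ratios were tested against 0 with lmFit and eBayes in limma over all measured probes, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 arrays each gene had 1 residual degree of freedom, to which the eBayes prior added 2.69. No exact permutation test of 2 ratios can pass that threshold. Errors are SDs over the 2 lines (n = 2) unless given as SE. A gene whose wild-type channel was not well above background on either array has only a bound. It is given as "at least N-fold", from channel values after loess and quantile normalization of average intensity, set against the mean over the arrays of the higher of 2 wild-type values, the dimmest signal well above background and the signal of the probe itself. Of the bounds given, all but that of Os03g0663900 rest on the signal of the probe itself and so equal its measured fold. Such bounds are open to dye bias.

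Gene names and descriptions are those of the array files, which can be old. None of the measured loci (0) matched a locus tag in the RefSeq gene table supplied with the data, so no newer symbols were added. OsbZIP39 (Os05g0411300), OsbZIP50 (Os06g0622700) and OsbZIP60 (Os07g0644100) were assigned to loci from prior knowledge before the data were examined, and nothing used here checks these assignments. The array describes the last 2 only as bZIP-domain factors and the first as a conserved hypothetical protein.

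The 18 gene lists, the tests, the alternatives and the rule for named genes were set before the data were examined, while the choice to treat a distinct 60-base sequence as a probe was made after. Named are the 3 OsbZIP loci; the 10 highest and 10 lowest genes by mean log2 ratio among those past the threshold with the same sign in both lines; from each list up to 4 members with the largest smaller of the 2 log2 sizes, where both lines have the same sign; and the 3 genes with the largest line difference in each direction. Genes named outside this rule are marked as chosen after their values were seen. Lists with at least 5 measured genes, 16 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. At this preset, camera compares the genes of a list with all other genes and takes genes as the units. Its p-values therefore do not measure the spread between the lines. With an estimated correlation camera has 1 residual degree of freedom. Its smallest unadjusted p was then 0.153, so the lack of a call there decides little. Each list median was also placed among 10000 random lists of the same size matched on intensity. Alternatives covered background correction, normalization, the filter on dim probes, the deposited log10 ratios, the choice of probe, the prior, the size threshold, the correlation used by camera and leaving out each line. Inclusion of probes printed under several genes, a fit of the 4 channels as separate samples, and 3 lists without part of their members, were added after the data were seen.

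The procedure was tested on simulated data for this comparison, with 200 of the 21690 genes changed on 2 simulated arrays. A list of 30 further genes was raised by 0.5 log2 units in each draw. Changes of 1 to 3 log2 units were tried first, and changes of 1 to 5 were added after that result was seen. A first draw had recovered few genes, so 10 draws of each were made, with the dyes as bright as in the arrays and with equal dyes, and all are given. With changes of 1 to 3 and dyes as in the arrays, 41.8% to 70.1% of the genes were called at a log2 change of 2 and 78.8% to 97.0% at 3. With equal dyes these shares were 2.99% to 59.7% and 50.0% to 95.5%. With changes of 1 to 5, the shares were 57.5% to 75.0% at 2 and 87.5% to 95.0% at 3 with dyes as in the arrays, and 50.0% to 72.5% and 82.5% to 95.0% with equal dyes. At least 90.0% of the genes were called at 4 and at least 92.5% at 5. At a log2 change of 1 at most 2.5% were called. None of the 200 changed genes was called in the wrong direction. Unchanged genes, with the 30 raised genes not counted among them, made up at most 10.4% of the calls of a draw. The simulated noise was independent between the arrays, without error from a shared wild type or dye bias of single genes. That share therefore need not hold for the real calls. Recovery thus differed between draws and with the other changes present. The median estimate at a log2 change of 2 lay between 1.83 and 1.88, so changes were understated.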

Results

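Shoots of seedlings overexpressing truncated OsbZIP39 were compared with wild-type shoots to ask which transcripts change when this ER stress factor is present in a truncated form. Each overexpressor line, 12 and 28, was hybridised once against wild-type RNA, which gave 2 ratios for each of 21690 measured genes. All values are log2 ratios of overexpressor over wild type, and p-values are limma's, adjusted by Benjamini-Hochberg. The unadjusted limma p was under 0.05 for 6700 of the 21690 genes. Unadjusted counts within a list are to be read against that share.

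The transgene itself was examined first. The only array probe of the locus taken as OsbZIP39 (Os05g0411300, 3 spots) had a log2 ratio of -0.70 in line 12 and -0.30 in line 28, with a mean of -0.50 ± 0.28 (SD, n = 2; adjusted p = 0.14). It did not pass the threshold. The probe sequence contains a stop codon in all 3 forward reading frames, so it lies at least partly outside an uninterrupted coding sequence. Both ratios were below 0, opposite to the overexpression that the labels name. Whether the probe lies within the truncated transgene is not known here, since the sequence of the construct was not used. A probe outside it would check nothing about its expression, so the labels stay unchecked, and the direction of every ratio rests on them. The bZIP-domain gene taken as OsbZIP50 (Os06g0622700), another factor of the ER stress response, rose by 2.68 in line 12 and 2.45 in line 28, a mean of 2.57 ± 0.16 (SD, n = 2; adjusted p = 0.030). The bZIP-domain gene taken as OsbZIP60 (Os07g0644100) had ratios of -0.31 and 0.16, a mean of -0.08 (adjusted p = 0.78) that turned to 0.30 with median centring alone. The list of ER stress transcription factors and sensors had 4 measured genes, too few to test, and Os06g0622700 was its 1 riser, also when adjusted over the list alone. The median of the list was -0.04 and its mean 0.50, which differ in sign.

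ER chaperones, which fold newly made secretory proteins, stood among the most strongly raised genes. Of 13 measured ER chaperone genes 10 rose, 0 fell and 3 did not pass the test; adjusted over the list alone, 11 rose and 1 fell. Their median log2 ratio was 2.85 in line 12 and 3.25 in line 28. An Hsp70 precursor (Os05g0428600) was 37.4-fold higher, with log2 ratios of 5.22 and 5.24 (mean 5.23 ± 0.01, SD, n = 2; adjusted p = 0.017). A calreticulin (Os03g0832200), a calcium-binding chaperone of the ER, rose by 4.78 ± 0.07. Calreticulin 3 precursor (Os05g0507300) rose by 3.93 ± 0.08 and luminal binding protein 2 precursor (Os05g0367800), an Hsp70 of the ER lumen, by 3.80 ± 0.16. The 3 members that did not pass, named after their values were seen, were another luminal binding protein 2 precursor (Os03g0710500, 1.20, adjusted p = 0.056, with its wild-type channel well above background on 1 of the 2 arrays), a calreticulin-interacting protein (Os07g0498800, 0.17, adjusted p = 0.37) and a member of the calreticulin/calnexin family (Os03g0807400, -0.47, adjusted p = 0.11). The list shift gave a camera adjusted p of 1.28e-10, and an adjusted p = 0.617 with an estimated correlation.

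**Figure D1:**
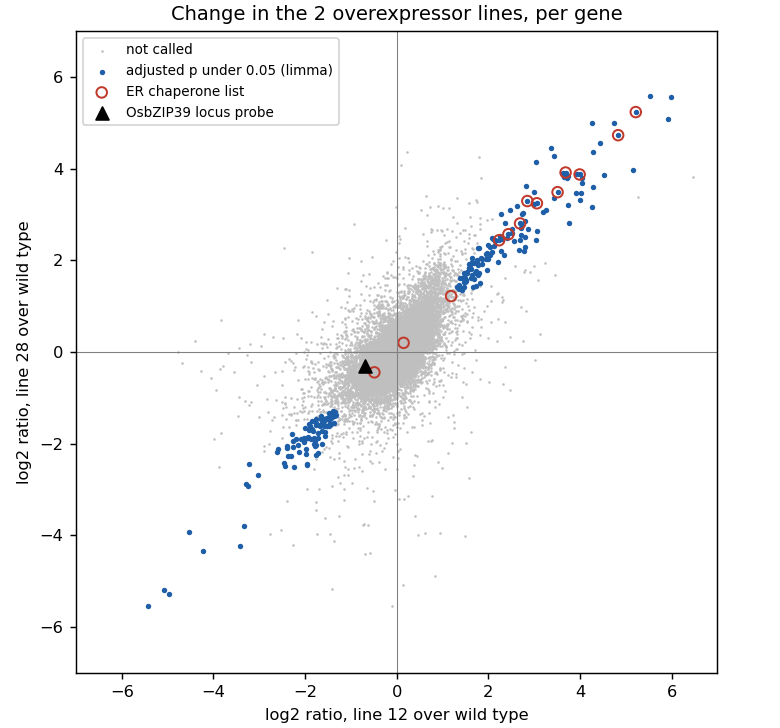
Log2 ratio of line 12 over wild type (horizontal axis) against that of line 28 over wild type (vertical axis) for the 21690 measured genes, 1 point per gene. The 225 genes past the adjusted p threshold of 0.05 are blue, the 13 ER chaperone genes are circled, and the triangle marks the probe of the locus taken as OsbZIP39; 10 of the circled genes lie among the blue points at the upper right.

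Some genes for other steps of the secretory pathway rose as well, while 7 of 11, 23 of 26 and 25 of 28 members of the next lists did not pass. Of 11 genes for disulfide formation in the ER, 4 rose and 0 fell (6 and 0 adjusted over the list alone). The risers were a protein disulfide-isomerase precursor (Os11g0199200, 3.12 ± 0.09), a thioredoxin-related protein (Os09g0451500, 2.91 ± 0.40), endoplasmic oxidoreductin 1 precursor (Os03g0733800, 2.03 ± 0.33), the oxidase that reoxidises disulfide isomerases, and another protein disulfide-isomerase precursor (Os05g0156300, 1.58 ± 0.20). Of 26 genes for ER translocation and N-glycosylation, 3 rose and 0 fell (11 and 0 adjusted over the list alone). These were SEC61 beta (Os01g0565900, 2.64 ± 0.11) and SEC61 alpha (Os03g0213100, 1.99 ± 0.05), parts of the channel through which proteins enter the ER, and the STT3 subunit of oligosaccharyl transferase (Os04g0675500, 1.55 ± 0.10). A second SEC61 alpha gene (Os09g0347500) had a ratio of 0.89 and did not pass (adjusted p = 0.075). Of 28 genes for the COPII and COPI vesicle coats, which carry cargo between ER and Golgi, 3 rose and 0 fell (9 and 0 adjusted over the list alone). They were Sec24-like CEF (Os11g0482100, 2.07 ± 0.06), a Sec13-like protein (Os02g0135800, 1.72 ± 0.13) and Sec23A (Os11g0433500, 1.60 ± 0.18), while a Sec23/Sec24 zinc finger gene (Os01g0321700) stood at 1.30. The medians of these 3 lists were 0.47, 0.38 and 0.33, with camera adjusted p of 2.67e-04, 1.75e-05 and 1.50e-05. With an estimated correlation the adjusted p = 0.617 for each. Median centring alone, which moved the median of all genes to 0.21 in line 12 and 0.22 in line 28, gave list medians of 0.88, 0.83 and 0.78.

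For ER-associated degradation, the removal of misfolded ER proteins, 0 of 14 genes rose or fell in limma over all genes tested (4 rose and 0 fell adjusted over the list alone, and 5 and 0 had an unadjusted p under 0.05). The list median was 0.12 (camera adjusted p = 0.15), and with median centring alone it was 0.36 and passed (adjusted p = 0.014). Its members named by the rule, none of which passed, were a Der1-like gene (Os03g0852200, 1.23, adjusted p = 0.054), a Sel1-like repeat gene (Os03g0259300, 0.82), a UBX-domain gene (Os10g0520600, 0.77) and a further Der1-like gene (Os05g0187800), at least 1.52-fold higher (adjusted p = 0.089) with its wild-type channel not well above background. Of 112 heat shock protein genes 6 rose and 0 fell (8 and 2 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.0065, and adjusted p = 0.617 with an estimated correlation). The median was 0.11 in line 12 and 0.20 in line 28, and 0.45 with median centring alone. Although the list was named for cytosolic proteins, 3 of its members and 2 of its risers are also in the ER chaperone list. Without those 3, left out after the values were seen, the median was 0.13 (camera adjusted p = 0.023, and adjusted p = 0.63 with an estimated correlation). The other risers included Hsp70 family genes Os06g0212900 (3.92 ± 0.19) and Os02g0710900 (3.11 ± 0.16).

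**Figure D2:**
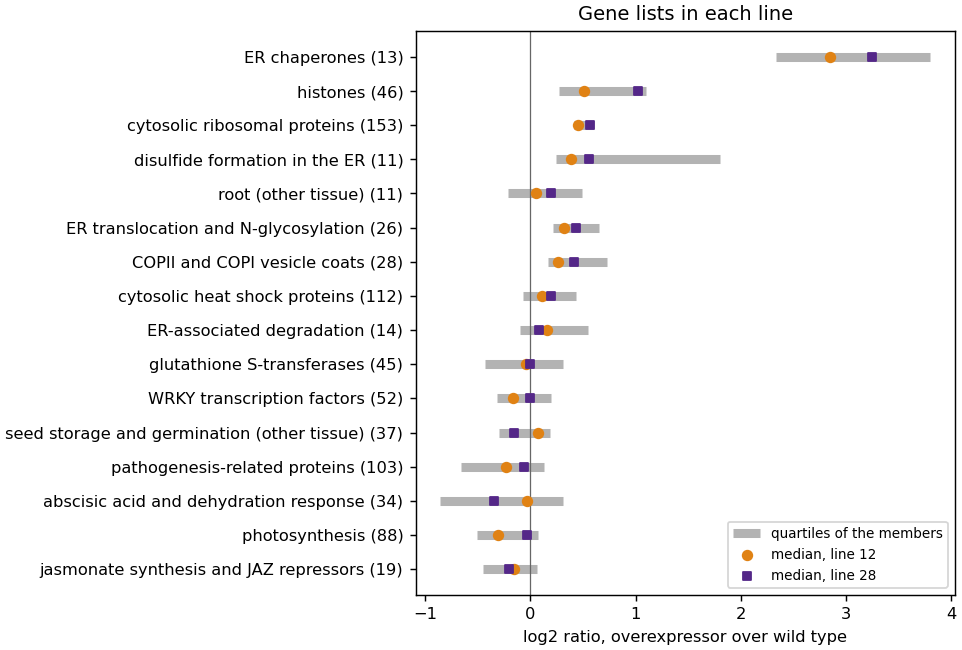
Median log2 ratio of overexpressor over wild type (horizontal axis) for the 16 tested gene lists, in line 12 (circles) and line 28 (squares), with the number of measured genes in parentheses. Grey bars span the members' means over both lines from the lower to the upper quartile; the ER chaperone medians of 2.85 and 3.25 lie apart from every other list shown.

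Across all genes, 225 passed the threshold, 132 higher and 93 lower in the overexpressors, each at least 2-fold changed in the same direction in both lines. Of the 132 that rose, the gene with the highest measured mean was an NADP-dependent malic enzyme (Os01g0743500, 5.78 ± 0.30, adjusted p = 0.017), which releases carbon dioxide from malate. Genes with only a bound could rank higher, so the highest place is not settled. A pair of early light-inducible protein genes, whose products protect chloroplasts under light stress, rose by 5.51 ± 0.59 (Os07g0178700) and 4.56 ± 0.83 (Os07g0178800). The line 28 array differed from the line 12 array for these genes by -1.84 and -1.65 in the wild-type channel and by -2.67 and -2.82 in the overexpressor channel. An oleosin family gene (Os03g0699000), for a coat protein of oil bodies, rose by 4.32 ± 0.05. Conserved hypothetical proteins Os09g0445600 (5.56 ± 0.04), Os02g0256200 (4.87 ± 0.17) and Os01g0767600 (4.63 ± 0.53) were also among the 10 highest, and Os03g0115800 was at least 22.6-fold higher (adjusted p = 0.017), with its wild-type channel not well above background.

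Of the 93 genes that fell, the gene with the lowest mean by its brightest probe was a transcript described as non-protein-coding (Os01g0322700, -5.48 ± 0.08, adjusted p = 0.017). Its other probe had -4.60, so its rank depends on the probe used. This transcript was followed by a beta-glucosidase aggregating factor (Os12g0247700, -5.14 ± 0.09) and a hypothetical protein (Os03g0129400, -5.13 ± 0.21). The probe named for the microRNA osa-miR528, which does not show the mature form, fell by 4.28 on the log2 scale (SD 0.08, n = 2). Copper transporter 1 (Os01g0770700), which takes copper into the cell, had a ratio of -4.24 ± 0.43. A DUF26 protein (Os04g0659300, -3.83 ± 0.57), a gene described as a molecular chaperone (Os03g0300600, -3.56 ± 0.33, with other probes between -2.46 and -2.29), an isoflavone reductase-like gene (Os01g0106400, -3.09 ± 0.30) and a Bowman-Birk trypsin inhibitor (Os01g0124000, -3.08 ± 0.23) also fell. The Gigantea homologue (Os01g0182600), a gene of the circadian clock, was the last of the 10 lowest at -2.87 ± 0.24, and its level differed between the arrays by 2.03 in the wild-type channel and 2.38 in the overexpressor channel. For the gene described as a molecular chaperone (Os03g0300600) these differences were 3.33 and 2.87.

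The count of genes differed between processing settings. With median centring in place of loess limma called 4991 genes higher and 1503 lower, a share of 76.9% higher against 58.7% in the main analysis, and with the scanner's own processed signals, which differ in background subtraction, detrending and dim-spot values as well as in dye normalization, it called 0. There 6308 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.0525. The 225 genes had the same sign under each of these settings.

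Genes whose descriptions match pathogenesis-related proteins had a negative median. Of 103 pathogenesis-related genes 0 rose, 3 fell and 100 did not pass (3 and 16 adjusted over the list alone), and the list median was -0.14 (camera adjusted p = 0.0043, and adjusted p = 0.617 with an estimated correlation). It was -0.23 in line 12 and -0.06 in line 28, with a median difference between the arrays (line 28 minus line 12) of -0.15 in the wild-type channel and 0.10 in the overexpressor channel. The 3 that fell were a thaumatin family gene (Os12g0569500, -2.83 ± 0.56, adjusted p = 0.048), a PRB1-2 precursor (Os01g0382400, -2.22 ± 0.24, adjusted p = 0.040) and a class III chitinase homologue (Os11g0700900, -1.65 ± 0.05, adjusted p = 0.042), the last named after its values were seen. A chitinase (Os01g0860500) had ratios of -3.87 and -2.50 (adjusted p = 0.067), but its other probes had means between -0.88 and 0.11. A gene described as a pathogenesis-related transcriptional factor with an ERF domain (Os09g0287000) had ratios of -3.84 and -1.76. Such members match by description and need not be defence proteins, and the list was not tested without them. Of 52 WRKY transcription factor genes 0 rose or fell in limma (2 and 3 adjusted over the list alone, and 9 and 7 at an unadjusted p under 0.05). WRKY 10 (Os01g0186000, -1.94) and WRKY 30 (Os08g0499300, -1.25) had negative ratios, and WRKY 45 (Os05g0322900, 1.32) and a further WRKY gene (Os09g0417600, 1.64, with other probes between 0.69 and 1.04) positive ones. The WRKY list median was -0.03 (camera adjusted p = 0.43), with -0.17 in line 12 and -0.0055 in line 28, and with median centring alone it was -0.06 and passed (adjusted p = 0.014). Kaurene synthase A (Os02g0278700, -0.26 in line 12 and -0.86 in line 28) was the only measured gene matched to diterpenoid phytoalexin synthesis. It matched by its description and need not act in that pathway. It was not tested as a list and did not pass (adjusted p = 0.16).

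Among 34 genes of the abscisic acid and dehydration response 2 rose and 0 fell (3 and 3 adjusted over the list alone). Dehydrin 9 (Os11g0451700) was at least 18.3-fold higher (adjusted p = 0.030), with its wild-type channel not well above background, and dehydrin COR410 (Os02g0669100) rose by 1.75 ± 0.03 (adjusted p = 0.040). A late embryogenesis abundant repeat gene (Os03g0322900, 2.58, adjusted p = 0.073) and an AP2-domain gene (Os03g0191900, -1.04, adjusted p = 0.071) did not pass. The list median was -0.16 (camera adjusted p = 0.38), with -0.04 in line 12 and -0.35 in line 28, and a median difference between the arrays of 0.20 in the wild-type channel and -0.10 in the overexpressor channel. It was -0.09 without the filter on dim probes and turned to 0.09 with median centring alone. Of 19 jasmonate genes 1 rose and 0 fell, with the same count adjusted over the list alone, and the median was -0.18 (camera adjusted p = 0.16). It turned to 0.11 with median centring alone, and without the filter on dim probes it was -0.19 and passed (adjusted p = 0.047). The riser was allene oxide synthase (Os02g0218800), an enzyme of jasmonate synthesis, at least 4.05-fold higher (adjusted p = 0.033) with its wild-type channel not well above background. Lipoxygenase genes Os08g0508800 (-2.80 in line 12 and -1.32 in line 28), Os12g0559200 (-0.83 and -2.51) and Os12g0560200 (-0.75 and -1.95) did not pass. Another probe of Os08g0508800 had a mean of -0.79, and those of Os12g0559200 had means between -1.19 and -0.74. Of 45 glutathione S-transferase genes 0 rose and 1 fell (1 and 5 adjusted over the list alone), with a median of 0.02 but a mean of -0.14 and a test direction below 0 (camera adjusted p = 0.38). The median was -0.04 in line 12, -0.00049 in line 28, -0.05 with the filter on both channels and 0.20 with median centring alone. The faller was GST 29 (Os01g0950300, -2.09 ± 0.08, adjusted p = 0.033), and GST 40 (Os07g0168300, -1.46 in line 12 and -3.98 in line 28), GST 19 (Os07g0468100, -1.03, and -0.66 for another probe) and GST 18 (Os12g0210300, -0.85) did not pass.

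Ribosomal protein and histone genes shifted as lists with no single gene past the threshold over all genes. The 153 cytosolic ribosomal protein genes had a median of 0.45 in line 12 and 0.57 in line 28, and 146 were above 0 in both lines (camera adjusted p = 9.14e-22, and adjusted p = 0.617 with an estimated correlation). Over all genes 0 rose or fell in limma, while 127 were higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 121 rose and 1 fell. Members named by the rule were 60S acidic protein P0 (Os11g0135400, 1.57), L30 (Os01g0812800, 1.21), L40 (Os09g0568400, 0.82) and another P0 gene (Os08g0130500, 0.82). The 46 histone genes had medians of 0.50 in line 12 and 1.02 in line 28 (camera adjusted p = 8.11e-09, and adjusted p = 0.617 with an estimated correlation). The median difference between the arrays was -0.49 in the wild-type channel and -0.05 in the overexpressor channel. Limma called 0 of them over all genes, with 33 higher and 0 lower at an unadjusted p under 0.05, and 31 and 0 adjusted over the list alone. Histone H2A.F/Z (Os10g0418000, 1.47), H4 (Os09g0433600, 1.24), H2A (Os03g0279200, 1.15) and H2B.2 (Os05g0574300, 1.14) were the histone genes named by the rule. The medians over both lines were 0.50 and 0.77, and median centring alone gave 1.12 and 1.27. None of the 8 list calls held with an estimated correlation, where 1 residual degree of freedom could hardly yield a call.

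The full photosynthesis list and the lists for other tissues did not pass camera. Of 88 genes matched to photosynthesis 0 rose or fell in limma (4 and 4 adjusted over the list alone, and 12 and 16 at an unadjusted p under 0.05). The median was -0.18 (camera adjusted p = 0.062), with -0.31 in line 12 and -0.03 in line 28, and a median difference between the arrays of -0.23 in the wild-type channel and 0.06 in the overexpressor channel. It turned to 0.39 with median centring alone, while with the mean of all probes it was -0.17 and passed (adjusted p = 0.044). Of these genes 27 are plastocyanin-like domain proteins, which need not act in photosynthesis, among them Os06g0681200 (-1.47), with its overexpressor channel well above background on 1 of the 2 arrays. Without these 27, left out after the values were seen, 61 genes had a median of -0.30 and passed (camera adjusted p = 0.010, and adjusted p = 0.617 with an estimated correlation). That median was -0.52 in line 12 and -0.04 in line 28, and it turned to 0.45 with median centring alone (adjusted p = 0.43). Os04g0235200, described as photosystem Q(B) protein, had a ratio of -1.82. Os04g0516200 and Os02g0811000, described as ribulose bisphosphate carboxylase large chain family, had ratios of 1.75 and 1.25, the former with its wild-type channel well above background on 1 of the 2 arrays. The descriptions alone do not show that these loci encode the working photosynthesis proteins. Of 37 genes matched to seed storage and germination 0 rose or fell in limma (1 and 2 adjusted over the list alone, and 5 and 5 at an unadjusted p under 0.05), with a median of -0.13 (camera adjusted p = 0.38). It was 0.07 in line 12, -0.15 in line 28 and -0.07 without the filter on dim probes, and turned to 0.20 with median centring alone. Of these 27 are lipid transfer or trypsin inhibitor family genes, such as Os07g0290200 (-1.71), Os01g0849000 (-1.05, and -0.51 for another probe), Os03g0103300 (0.94 in line 12 and 1.90 in line 28) and Os03g0663900, at least 2.06-fold higher (adjusted p = 0.075) with its wild-type channel not well above background. The 10 others had a median of -0.09 (camera adjusted p = 0.56), a subset also chosen after the values were seen. Of 11 root genes 0 rose or fell in limma (0 and 1 adjusted over the list alone, and 3 and 1 at an unadjusted p under 0.05), with a median of 0.39 (camera adjusted p = 0.65). It was 0.05 in line 12, 0.19 in line 28, 0.09 with median centring alone, 0.16 with the filter on both channels and 0.20 without a filter on dim probes. They included root-specific RCc2 genes Os10g0551800 (-1.14) and Os10g0552300 (0.63 in line 12 and 0.25 in line 28), RCc3 (Os02g0662000, 0.75 and 0.31) and nicotianamine synthase 1 (Os03g0307200, 0.39), whose wild-type channel was well above background on 1 of the 2 arrays and whose ratio turned to -0.03 with median centring alone.

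Among random lists of the same size and intensity, the 7 lists called higher had medians at percentiles 99.8 to 100 and the pathogenesis-related list at 0.06. Of the lists that did not pass camera, photosynthesis lay at percentile 0.08, dehydration at 1.27, jasmonate at 2.75, seed genes at 3.71 and root genes at 99.6, and WRKY, glutathione S-transferase and ER-associated degradation genes at 20.6, 55.7 and 82.7. The percentile describes these arrays and takes genes as independent, so an extreme one is not a call.

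The lines were then set against each other. Across genes, which are not independent replicates, their log2 ratios had a Pearson r of 0.67 and a Spearman rho of 0.66, with no p given, and 75.2% of genes had the same sign. In both lines 357 genes were at least 2-fold higher and 312 at least 2-fold lower. With median centring alone these were 969 and 216, and with processed signals 826 and 585. Independent lists of the sizes found in each line by the main analysis would share 27.4 and 27.5. Unchanged lines simulated against 1 shared wild-type sample had on average 183 genes at least 2-fold higher and 184 at least 2-fold lower in both lines, in 100 simulations. Line 12 alone had 532 higher and 802 lower genes, and line 28 alone had 1118 and 743. The same simulations gave r = 0.50 and a covariance of 0.122, against an observed covariance of 0.242. They gave the wild type the same spread per gene as each line. That choice fixed the simulated r and covariance in advance, and the simulated counts depend on it. The simulated values leave out real effects and assume 1 wild-type sample on both arrays, which the labels do not give, and the counts for independent lists leave out any sharing. Over all genes the wild-type channel differed between the arrays by an SD of 0.54, more than the overexpressor channel at 0.39. In Os01g0702000 it differed by 6.08. These values argue against 1 wild-type RNA sample on both arrays, so the setting of the simulations departs from these data. Any other error common to both wild-type samples may still add to the overlap, and with 1 wild-type hybridisation per array it cannot be split off.

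The difference between the lines can be given only as values, since each line had 1 array. Log2 ratios differed by at least 2 for 167 genes, 90 higher and 77 lower in line 28. The largest differences above line 12 were in expansin-related protein 2 precursor (Os09g0472900, -4.78 in line 12 and 0.01 in line 28, each channel well above background on 1 of the 2 arrays) and in PBZ1 genes of the defence response, Os12g0555300 (-2.46 and 2.27) and Os12g0555500 (-4.39 and 0.23). The largest below were in a conserved hypothetical protein (Os01g0702000, 0.83 and -4.90), the thiamine synthesis gene thiC (Os03g0679700, 1.48 and -4.02) and a Myb-domain gene (Os01g0971800, -0.10 and -5.55). The 4 other probes of thiC had means over both lines between -2.88 and -1.23, against -1.27 for the probe used. These means do not show whether the other probes differed between the lines. In 83.2% of the 167 genes the wild-type channel differed more between the arrays than the overexpressor channel did. Over all genes the between-array difference had an SD of 0.54 in the wild-type channel and 0.39 in the overexpressor channel.

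**Figure D3:**
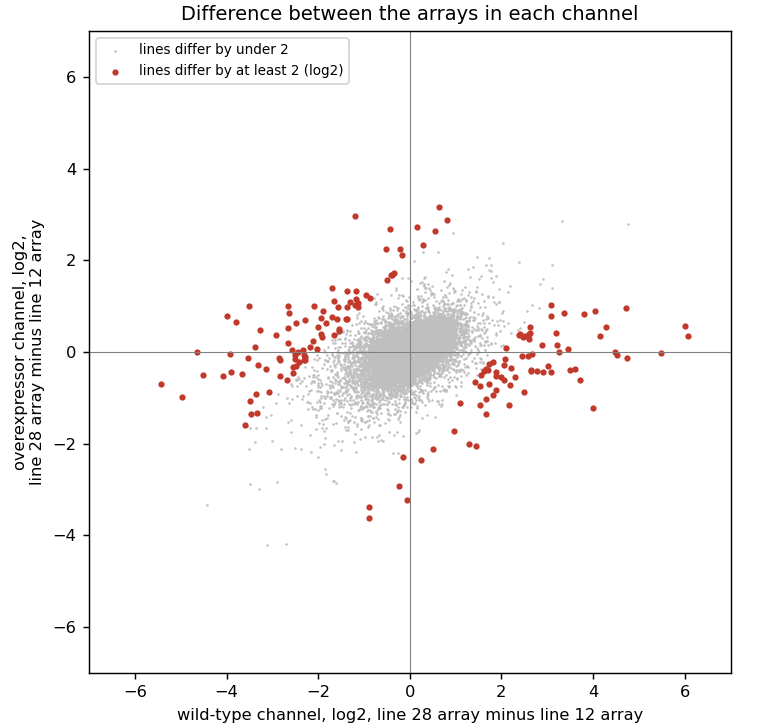
Difference between the line 28 array and the line 12 array (log2) in the wild-type channel (horizontal axis) and in the overexpressor channel (vertical axis), 1 point per gene, after loess and quantile normalization of average intensity. The 167 genes whose log2 ratio differed between the lines by at least 2 are red, and 83.2% of them moved more along the wild-type axis than along the overexpressor axis.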

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

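The inclusion of probes printed under several genes, the fit of the 4 channels as separate samples, and the lists without some of their members, were chosen after the data were seen. The genes changed in the overexpressors, 132 higher and 93 lower, stayed within 1.5 times of those counts without background correction, with either filter on dim probes, with probes under several genes, and with a trend or robust prior. With normexp offset 16 the lower count was 57. The mean of all probes gave 86 and 43, separate channels 74 and 18, and median centring alone 4991 and 1503. The scanner's processed signals gave 0 and 0, as did the deposited table, where limma found 6308 and 6303 genes at an unadjusted p under 0.05 and the smallest adjusted p was 0.0525 and 0.0533. The cause was not tested for these. Median centring alone moved the median of all genes to 0.21 in line 12 and 0.22 in line 28. Each of the 225 called genes that a single-ratio setting measured kept its sign, 200 of them under the filter on both channels. Separate channels called 92 genes, all among the 225. With 1 line left out there is no spread, so no gene test and no correlation was computed.

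The 357 and 312 genes at least 2-fold changed in both lines became 826 and 585 with processed signals, 824 and 583 with the deposited table, and 969 and 216 with median centring alone. At 1.5-fold they were 1274 and 998, and at 3-fold 132 and 81, by construction. In 1 line alone the higher count was 532 to 1118 and the lower count 743 to 802. The correlation between lines ranged from 0.64 to 0.75. The OsbZIP39 probe ranged from -0.56 to -0.20 over the settings and from -0.70 to -0.30 in single lines, and never passed the threshold. Each of the 8 called lists kept its call in the planned settings where camera was run, except with an estimated correlation. There 0 lists passed in either direction, and 1 residual degree of freedom leaves little information. Camera was not run with 1 line left out. The lower count was 2 lists with median centring, no filter on dim probes, the mean of all probes or photosynthesis without plastocyanin-like members, and median centring gave 8 higher.

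Some values that had not passed turned their sign, and the cause was not tested. Median centring alone gave list medians of 0.39 for photosynthesis, 0.088 for dehydration, 0.11 for jasmonate and 0.20 for seed genes, and log2 ratios of 0.30 for Os07g0644100 and -0.028 for Os03g0307200. The glutathione S-transferase median was -0.047 with the filter on both channels and between -0.044 and -0.00049 in single lines, and the seed median was between -0.15 and 0.070 in single lines. Os12g0555300, with a mean of -0.09, had 0.0914 with processed signals, 0.0914 with the deposited table and 0.28 with median centring. The ratio within each array already pairs overexpressor with wild type, and separate channels drop that pairing. Signal over background leaves 15 called genes with only a bound.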

Other observations

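The genes in this part, apart from those the report names, were chosen after their values were seen, and so were the copper counts, the tests on the wild-type channel, on other probes, on clock genes and on a trend with GC content or intensity, and the median centring and camera values of the division genes. Among 81 measured genes matched to copper proteins or superoxide dismutases, probes named for microRNAs included, 0 rose and 3 fell in limma. At an unadjusted p under 0.05, 12 were higher and 12 lower, a share similar to the 6700 of 21690 over all genes. The microRNA probes do not show the mature form. The 3 that fell were copper transporter 1 (Os01g0770700, -4.24 ± 0.43, SD, n = 2, adjusted p = 0.029), the copper chaperone homologue CCH Os02g0530100 (-2.05 ± 0.09, adjusted p = 0.035) and the osa-miR528 probe (-4.28 ± 0.08, adjusted p = 0.017). The other CCH homologue (Os08g0405700) had 1.04 (adjusted p = 0.068). Probes for osa-miR398b and osa-miR408 had -1.39 and -1.06 (adjusted p = 0.068 and 0.085), with other probes between -1.68 and -0.09 and between -2.13 and -0.78. Copper/zinc superoxide dismutases Os03g0351500, Os07g0665200 and Os08g0561700 had 0.50, 0.48 and 0.58 (adjusted p = 0.105, 0.113 and 0.108), while another (Os04g0573200) had 0.16 and a superoxide dismutase with no metal named (Os03g0219200) had -0.26 (adjusted p = 0.43 and 0.24). All 3 measured early light-inducible genes rose, Os01g0246400 by 3.71 ± 0.78 (adjusted p = 0.049), which differed between the arrays by -3.11 in the wild-type channel and -4.22 in the overexpressor channel.

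The 167 genes that differed between the lines by at least 2 log2 units may reflect wild-type RNA that was not the same on both arrays. In 83.2% of them the wild-type channel differed more between the arrays, with a median size of 2.31 against 0.55 in the overexpressor channel. In the 31 of these genes with another probe sharing no 20 bases, all 42 other probes differed the same way, by a median of 1.75. That argues against a fault of single probes for these 31 genes, and it stays open for the rest of the 167. A candidate explanation is harvest at different times of day, as 6 clock genes not noticed at first, though picked by locus from prior knowledge once other clock genes had been seen, had a median wild-type difference of 1.37 against 0.24 over all genes, at percentile 100 of intensity-matched random lists. Their overexpressor difference also lay at percentile 100, so this hypothesis is not special to the wild type, and no label gives a harvest time.

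Dye bias of single probes would leave other probes of the called genes near 0. In the 41 called genes with another measured probe sharing no 20 bases, all 64 other probes moved in the called direction, by a median of 1.66, which argues against such bias for these 41 genes. It stays open for the other 184, since the dyes were not swapped. A difference in harvest time between overexpressor and wild type also stays open and was not tested, since 5 of the same 6 clock genes were lower in the overexpressor on both arrays, the Myb-domain gene Os08g0157600, taken as a clock gene, had log2 ratios of 1.79 and 4.25, and the Gigantea homologue had -3.04 and -2.70. An effect of the transgene on the clock stays open as well.

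The ribosomal protein and histone lists were higher with no called member. If a trend with GC content or intensity left after loess had raised these lists, its removal would lower their medians. Loess already fits intensity, and the trend left explained 0.914% of the variance. Its removal kept at least 102.9% of each median, with 0.50 becoming 0.55 for ribosomal protein genes and 0.77 becoming 0.79 for histone genes. Both lists also lay at percentile 100 of random lists matched on intensity. These values argue against such a remaining trend as the source of the higher medians of these lists. Median centring alone gave medians of 1.12 and 1.27 against 0.50 and 0.77, with 0.21 over all genes, so their size depends on the normalization. A larger share of dividing tissue in the overexpressor shoots would raise division genes. The median of 98 such genes was 0.31, at percentile 100 of matched random lists. With median centring alone it was 0.63, also at percentile 100. Camera gave an adjusted p = 6.90e-07, and an adjusted p = 0.605 with an estimated correlation. In limma 0 of them passed, and 46 were higher and 5 lower at an unadjusted p under 0.05. Changes as small as these medians could hardly be called, since the simulations called at most 2.5% of genes at a log2 change of 1. The larger share of dividing tissue remains a hypothesis, because root genes also reached percentile 99.6, with a camera adjusted p of 0.65. The histone median of 0.50 in line 12 and 1.02 in line 28 differed between the arrays mostly in the wild-type channel (-0.49 against -0.05). Dye bias shared by such genes stays open as well. The loss of all list calls with an estimated correlation decides little, since camera then had 1 residual degree of freedom.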
